A study of Mus musculus with 2 samples.

How the data were processed

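Droplet single-cell RNA sequencing was made from 1 library of mouse prostate tumour and 1 library of normal tissue adjacent to tumour. Per the labels, both tissues were digested with collagenase at 1 mg/ml for 45 min and passed through a 40 µm strainer, sorted CD45+ and CD45- cells were loaded together in 1 channel, and cDNA was amplified for 14 cycles and sequenced to at least 10000 reads per cell on a NextSeq500. The deposited matrices hold raw UMI counts per gene and cell barcode, written by Cell Ranger 4.0.0 per the file headers. The labels also name R 4.0.3 and Seurat 3.2.2 for the authors' own processing, whose output was not used here. The submitters' notes list GRCh38, a human build, while every feature is a mouse gene. The mouse build, the annotation release and the parameters of cell calling are not given in the sources used here, so no coordinates are printed. GENCODE vM21 (assembly GRCm38) served only for gene names and for which genes lie beside each other.

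Each matrix covers 32285 mouse genes. The normal adjacent library holds 6553 barcodes and 77855775 UMIs, with a median of 6017 UMIs and 2039 genes per barcode. The tumour library holds 8237 barcodes and 92188538 UMIs, with medians of 6015 and 2033. Barcodes with under 200 detected genes (21 and 55) or over 20% mitochondrial UMIs (337 and 459) were removed, 344 and 469 in all. Scrublet, run per library in scanpy, marked 1 and 0 barcodes, under 0.5% of cells, and so has not worked. Doublets were therefore weighed through cells that carry markers of 2 lineages. A lineage counted as carried with at least 3 UMIs of its markers and at least 10% of that lineage's median level (5% for neutrophil markers), over 6 marker sets. Such cells stayed in the main analysis and made up 27.1% and 30.6% of cells. A doublet rate of 0.8% per 1000 barcodes, the one set for removing the highest Scrublet scores, would give far fewer. The share of such cells is therefore not a measure of doublets alone.

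Cells of both libraries were clustered together without batch correction, on 2000 variable genes, counts scaled to 10000 per cell and log transformed, 30 principal components, 15 neighbours and Leiden resolution 1. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Lymphoid, myeloid and non-immune cells were clustered again on their own. A cluster was named X-like by reading its genes against 28 fixed marker sets, of which at least 3 own markers had to be detected. It stayed without a class where its 10 leading genes by fold went against a name or held more markers of another type, and 6 immune clusters and the mixed non-immune cells were kept apart because most of their cells carried markers of 2 lineages. This was not applied to every cluster. Such cells were also 43 of the 85 in the plasma-like class, which kept its name, 102 of 116 and 190 of 220 in a myeloid cluster led by Retnla and Lyz1, and 105 of 176 and 151 of 293 cycling cells. Of the clusters with a name, 2 neutrophil-like, 2 fibroblast-like and the innate lymphoid-like one had none of their own markers among the 10 leading genes. Clusters outside the named classes held 42.8% and 41.9% of immune cells and 58% and 56.7% of non-immune cells. The clusters kept apart as mixed held 16.3% and 17.9% of immune cells and 7.27% and 12.2% of non-immune cells.

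Shares are given within immune, lymphoid, myeloid or non-immune cells, with exact Clopper-Pearson intervals, and differences of shares with Newcombe intervals. UMIs were summed per library and class for 13 classes with at least 50 cells in both libraries. CPM has exact Poisson intervals, and ratios of CPM exact conditional binomial intervals, at 95%. Against a count of 0 the floor was 3 counts. With 1 library per group no test between groups was possible, and no p-value or count of changed genes is given. Named genes have at least 50 UMIs over both libraries, a CPM of at least 50 in the higher library and a CPM of at least 5% of that in the highest class of the same library. They were ranked by the interval bound nearest 1, and the first 12 each way were eligible in 3 classes (neutrophil-like, macrophage-like, luminal progenitor-like) and the first 5 each way in the others. Mitochondrial, ribosomal protein, haemoglobin and receptor segment genes, genes without a symbol of their own and sex-linked genes were left out. Of the 24 fixed gene lists, 2 to 4 members each are named whatever their size, and which of them was chosen after their values were seen. Results for a few single genes are not reported here. The files hold 291 of the 294 list genes and 204 of the 205 marker genes.

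A list median is the median log2 ratio over at least 4 members with at least 20 UMIs, with 0.5 UMIs added. Its percentile among 10000 random lists matched in 10 expression groups is a description of these libraries. Of 147 lists by class, 46 lay outside the central 95% of random lists, where 7.4 would by chance if genes varied independently of each other. The 38 that are drawn were chosen after their values were seen, and hold 30 of those 46. Some of the lists not drawn are given in the text as well. Cells of each class were also dealt at random into 2 sets of the libraries' sizes 200 times. A list was set against the central 95% of dealt medians, and the last eligible gene each way against the 95th or the 5th percentile of dealt bounds. Over all 147 lists, 33 medians lay outside the dealt range, 19 of the chosen 38 and 14 of the other 109, and each of these 33 is given in the text. Of the 33, 7 lay within the central 95% of random lists. Dealt ranges could be far wider than those of random lists. For interferon genes in B-like cells they were -1.00 to 0.96 against -0.17 to 0.22. The 7.4 is therefore too low as a chance number. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with shallower cells left out and B-like cells as background.

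The intervals were tested on simulated data for the macrophage-like comparison. Counts were drawn from the Poisson model that the intervals assume, so this checks their computation and not the spread between cells. The intervals held the true ratio for 8197 of 8531 genes, and left out 1 for 55 of 65 genes changed 1.5-fold and 64 of 66 changed 2-fold. Of 400 unchanged lists, 10 lay outside the random range. With macrophage-like cells dealt at random, the intervals held 1 for 90.4% of genes, less than their nominal 95%. This coverage was not measured in the smaller classes.

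The filters, markers, lists, rule for named genes and statistics were fixed before the data were examined. The alternatives fixed then were a mitochondrial maximum of 10%, at least 500 genes, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered alone, a median of ratios size factor, thinned cells, a total without abundant and stress genes, 5% free RNA subtracted, and list minimums of 5 and 50 UMIs. Chosen after the data were seen were the definition of mixed cells, the dealt cells and the rule that no value under 20 UMIs is read in an alternative. So were the splitting of NK-like and luminal-like clusters by their leading genes and 6 further kinds of alternative. The marker sets for mixed cells were trimmed once, because a first version with Ccr7, Fscn1 and fibroblast markers marked most B-like and basal-like cells.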

Results

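Single-cell RNA sequencing counted transcripts in 2 libraries of mouse prostate, 1 from tumour tissue and 1 from normal tissue adjacent to tumour. The comparison asks how the immune infiltrate of the tumour differed from that of the adjacent tissue. CD45+ cells (leukocytes) and CD45- cells were sorted and loaded together, so sorting and loading set the ratio of immune to non-immune cells. The normal adjacent library held 77855775 UMIs (unique molecular identifiers, which count molecules) in 6553 barcodes, with a median of 6017 per barcode. The tumour library held 92188538 UMIs in 8237 barcodes, with a median of 6015. After filtering, 6208 and 7768 cells were left, of which 5658 and 6926 were immune and 550 and 842 were not. There were no replicates, so all differences are between 1 library and another, and the 95% intervals in parentheses cover counting error only. Where 2 values are paired, the normal adjacent library comes first. Cell classes were named X-like from fixed markers, and expression is given as CPM, the UMIs of a gene over all UMIs of the class on the usual CPM scale.

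Neutrophil-like cells took a larger share of immune cells in the tumour library, and B-like, CD8 T-like, NK-like and regulatory T-like cells a smaller one. The neutrophil-like share went from 13.2% (12.3 to 14.1) to 20.2% (19.3 to 21.2), a difference of 7.01 points (5.71 to 8.30). B-like cells made up 6.88% and 3.41%, a difference of -3.47 points (-4.27 to -2.69), and CD8 T-like cells 5.50% and 2.60%, a difference of -2.90 points (-3.61 to -2.21). The CD8 T-like difference was -1.94 points when each library was clustered alone. NK-like cells differed by -1.30 points (-1.94 to -0.682), which was -2.91 points with cells that carried markers of 2 lineages removed and -2.44 points with at least 500 genes per cell. The difference was -0.520 points (-1.04 to -0.0180) in CD4 T-like cells, -1.19 points with each library alone and -0.00083 points at a Leiden resolution of 2. When the 1 barcode that Scrublet marked was put back and cells clustered anew, CD4 T-like cells made up 0.972% and 0.953%. Regulatory T-like cells, from 58 and 27 cells, differed by -0.635 points (-0.957 to -0.344). With each library clustered alone no tumour cluster was named so, and the counts were 61 and 0 cells. Plasma-like cells, the antibody secretors, were 16 and 69 cells, or 0.283% and 0.996%, and 9 and 34 of them carried markers of 2 lineages. That difference of 0.713 points (0.441 to 0.998) turned to -0.0168 points when receptor segment genes and Prss2 were left out of clustering. Conventional dendritic-like cells differed by 1.35 points (0.450 to 2.23). Monocyte-like cells stood at 2.42% and 2.44%, migratory dendritic-like cells at 2.03% and 2.12% and gamma delta T-like cells at 4.26% and 4.16%, and the interval of each difference included 0. The sign of the monocyte-like difference turned under 2 of 9 settings. The gamma delta T-like difference of -0.101 points was above 0 under 8 of 9 settings, and was 0.869 points (0.0767 to 1.65) with each library alone, so no direction is read from it. Clusters given no class name, cycling cells included, held 42.8% and 41.9% of immune cells.

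**Figure D1:**
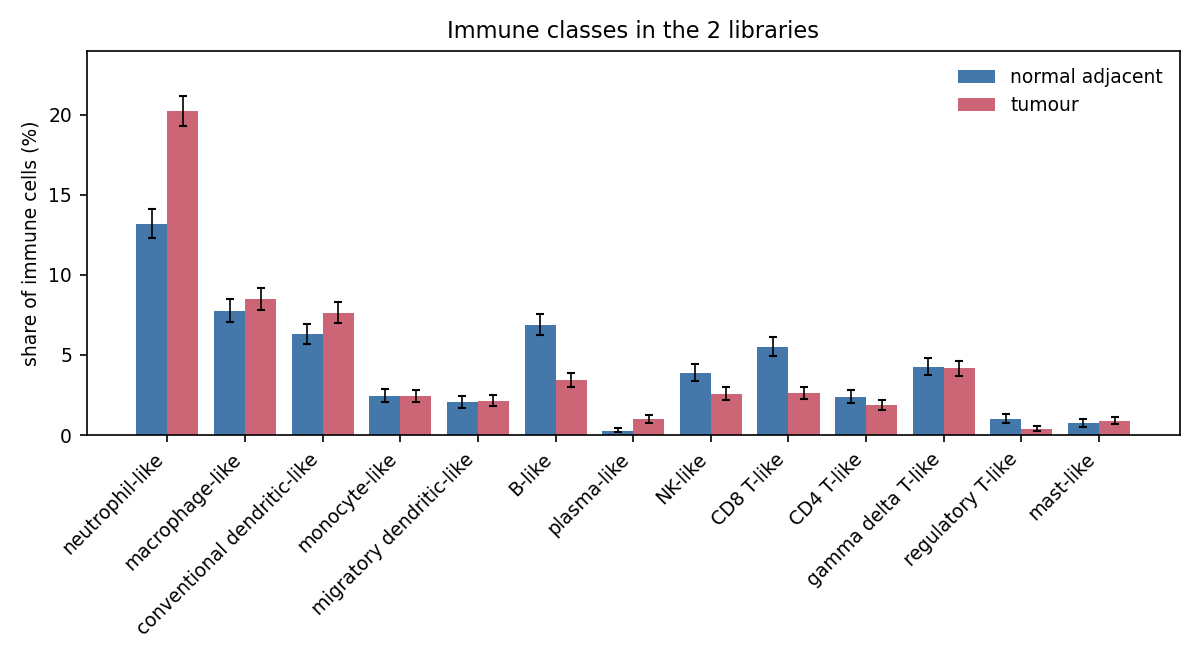
Shares of immune cells (%) held by 13 named classes in the normal adjacent (blue) and tumour (red) libraries, with exact 95% intervals for counting error as error bars. Neutrophil-like cells made up 13.2% and 20.2%, B-like cells 6.88% and 3.41% and CD8 T-like cells 5.50% and 2.60%.

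T, NK and innate lymphoid cells numbered 2064 and 1839 without the clusters kept apart as mixed and without the cycling cells. Among them CD8 T-like cells again had a lower share in the tumour library, as did regulatory T-like cells. Gamma delta T-like cells had a higher one, although their share of all immune cells was 4.26% and 4.16%, with no direction read. CD8 T-like cells made up 15.1% and 9.79%, a difference of -5.28 points (-7.33 to -3.21), which was -2.63 points with each library clustered alone. Cd8a had a UMI in 84 of 176 and 124 of 293 cycling cells, which the CD8 T-like shares leave out. The size of the CD8 T-like difference with such cells counted was not measured. Gamma delta T-like cells, marked by Trdc, Trdv4 and Il17a, made up 11.7% and 15.7%, a difference of 3.98 points (1.83 to 6.16). With each library clustered alone that difference was 7.55 points. Regulatory T-like cells made up 2.81% and 1.47%, a difference of -1.34 points (-2.27 to -0.430). CD4 T-like cells (6.49% and 6.96%) and NK-like cells (10.6% and 9.68%) had differences whose intervals included 0. A cluster led by Il17a and Zbtb16 that was kept apart from the gamma delta T-like class held 10.2% and 13.4%.

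Myeloid cells numbered 2052 and 3187 without the clusters kept apart as mixed and without the cycling cells. Among them neutrophil-like cells made up 36.4% and 43.9%, a difference of 7.53 points (4.81 to 10.2). Macrophage-like cells made up 21.4% and 18.4%, a difference of -2.98 points (-5.22 to -0.768), and monocyte-like cells 6.68% and 5.30%, a difference of -1.37 points (-2.74 to -0.0712). With each library clustered alone the neutrophil-like difference was 2.95 points and the macrophage-like difference -6.86 points. A cluster led by macrophage genes (Apoe, Ccl7, Cx3cr1) was kept out of the class because 89.6% of its cells carried markers of a second lineage. It held 254 and 469 cells, or 4.49% and 6.77% of immune cells, and is not among the myeloid cells counted above. The lower macrophage-like share of myeloid cells was measured for the named class, without that cluster. With cells that carried markers of 2 lineages removed, macrophage-like cells made up 30.2% and 28.4% of myeloid cells. With that cluster the macrophage-like share of immune cells was 12.2% and 15.2%. Without it the share was 7.76% and 8.48%, a difference of 0.716 points (-0.247 to 1.67). That difference was 3.34 points with 2-lineage cells removed and below 0 with each library alone. Conventional dendritic-like (17.3% and 16.6%) and migratory dendritic-like cells (5.60% and 4.61%) had differences whose intervals included 0.

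Non-immune cells were few, and the named epithelial and stromal classes had similar shares of them. Luminal progenitor-like cells, marked by Krt4 and Psca, made up 13.8% and 14.1%, basal-like cells (Krt5, Krt14) 10.5% and 13.5% and fibroblast-like cells 9.82% and 9.62%. The basal-like difference was 2.99 points (-0.571 to 6.37), and the intervals of the other differences also included 0. The sign of the luminal progenitor-like difference turned under 3 of 9 settings. That of the fibroblast-like difference, -0.198 points, turned under 8 of 9, so no direction is read from it. With each library clustered alone the luminal progenitor-like difference was -5.69 points. Luminal-like cells numbered 16 and 15, and seminal vesicle-like cells 27 and 36. Clusters given no class name held 58% and 56.7% of non-immune cells. The largest of these in the normal adjacent library, an epithelial cluster with a median of 751 and 769 UMIs, held 16.4% and 8.43%.

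Neutrophil-like cells of the tumour library had lower levels of inflammatory cytokines and of the heat shock genes Hspa1a and Hspa1b, and higher levels of tissue-resident macrophage genes. Tnf (ENSMUSG00000024401), an inflammatory cytokine, was 2.70-fold (2.51 to 2.91) lower, at 862 against 319 CPM. Wfdc17 (ENSMUSG00000069792), a whey acidic protein family member, was 2.73-fold (2.59 to 2.88) lower and Hspa1a (ENSMUSG00000091971), a heat shock chaperone, 4.85-fold (4.12 to 5.72) lower. Hspa1b was 3.72-fold (2.97 to 4.69) lower. Thbs1 was 1.67-fold (1.61 to 1.74) higher, Egr3 1.83-fold (1.55 to 2.17) higher and the integrin gene Itgal 1.72-fold (1.46 to 2.02) higher. Of the inflammatory cytokine and chemokine list, 13 of 13 members were lower, with a median log2 ratio of -0.37 (percentile 0, random deals -0.14 to 0.17). Il1a was 1.73-fold (1.62 to 1.85) lower, Ccl3 1.35-fold (1.32 to 1.38) lower and Cxcl2 1.31-fold (1.30 to 1.33) lower. Il1b counts among the lower members but was level, at 10153 against 10115 CPM, with an interval that included 1, and its sign turned under some settings. Hypoxia and glycolysis genes were lower in 10 of 13 members (median -0.30, random deals -0.10 to 0.11), among them Ero1l (1.68-fold, 1.5 to 1.88), Bnip3 (1.51-fold, 1.29 to 1.77) and Eno1 (1.36-fold, 1.23 to 1.5). Dissociation stress genes were lower in 12 of 16 members (median -0.14, random deals -0.11 to 0.09), and Nr4a1 was the largest exception, 1.43-fold (1.33 to 1.53) higher.

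Cells with a Tnf UMI at 1000 UMIs per cell made up 21.6% and 15.7% of neutrophil-like cells, against 1.36% and 1.29% of B-like cells. Without thinning the neutrophil-like shares were 34.4% and 26.4%, and thinning left out 47 and 52 shallower cells. Wfdc17 was found in 43.9% and 24.1% of thinned neutrophil-like cells, unthinned in 54.9% and 36.1%, against 7.63% and 3.86% of thinned B-like cells. Hspa1a was found in 4.71% and 2.37% of thinned neutrophil-like cells, unthinned in 13% and 5.14%, close to the 2.45% and 1.29% of thinned B-like cells (15.2% and 8.90% unthinned). Median depths were 2920 and 2304 UMIs in neutrophil-like and 5122 and 5250 in B-like cells. All 8 of the 8 measured genes of tissue-resident macrophages were higher in tumour neutrophil-like cells (median 0.86, random deals -0.35 to 0.41), with F13a1 at 3.65-fold (1.70 to 8.96) and Pf4 at 1.89-fold (1.42 to 2.56). The macrophage genes Ccl8 (2.50-fold, 1.90 to 3.34), Ccl12 (2.07-fold, 1.66 to 2.61) and C1qa (1.58-fold, 1.46 to 1.72) were also higher, and C1qa was 1.51-fold (1.41 to 1.62) higher in B-like cells and 1.39-fold (1.14 to 1.70) higher in CD8 T-like cells too, while its intervals included 1 in CD4 T-like, gamma delta T-like and NK-like cells. Lipid-associated macrophage genes went both ways (6 of 14 higher), with a median below random deals (median -0.25, random deals -0.11 to 0.15, percentile 0.150). Genes of alternative activation and suppression also went both ways (5 of 12 higher, median -0.17, random deals -0.15 to 0.17), with a median within matched random lists (percentile 3.75). Genes of MHC class II antigen presentation were higher (8 of 9 higher, median 0.34, random deals -0.32 to 0.31). Free RNA and doublets were not excluded for this MHC class II list, and neutrophil-like cells were shallower in the tumour library. The log2 ratio of Apoe in neutrophil-like cells was 0.91, and 0.23 with cells that carried markers of 2 lineages removed. Such cells made up 15.8% and 19% of neutrophil-like cells. The type I interferon list (6 of 12 higher, median -0.02, random deals -0.21 to 0.18) and the granule and suppressor list (6 of 16 higher, median -0.07, random deals -0.09 to 0.12) lay within the range of random deals. With thinned cells the interferon median was 0.12. The class joined 4 clusters, 1 of them led by the interferon genes Rsad2 and Ifit1 and another, with 167 of 747 and 169 of 1400 cells, by Prok2 and Itpr2, with Hilpda and Ccl3 among its leading genes. The make-up of the class therefore differed between the libraries, which the lower Ccl3 and hypoxia genes may follow. Ranked without the 5% rule, the 12th gene each way had an interval bound of 1.46 (higher) and 0.519 (lower). Random deals of the same cells reached 1.26 and 0.751.

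Macrophage-like cells of the tumour library had higher levels of Il12b, Cxcl1 and Gpr84 and lower levels of Hspa1a, Hspa1b and Ccl5. Il12b (ENSMUSG00000004296), a subunit of interleukins that drive T cell responses, was 2.44-fold (2.10 to 2.86) higher, at 54.2 against 132 CPM. Cxcl1 (ENSMUSG00000029380), a neutrophil attractant, was 2.02-fold (1.83 to 2.22) higher, Gpr84 2.26-fold (1.92 to 2.69) higher, Il1a 1.51-fold (1.38 to 1.65) higher, Igf1 1.76-fold (1.41 to 2.20) higher and Lpl 1.58-fold (1.40 to 1.78) higher. Retnla (ENSMUSG00000061100), a gene of alternatively activated macrophages, was 5.60-fold (4.66 to 6.78) higher, but 1 cell held 40.3% of its tumour UMIs, and the log2 ratio of Retnla in macrophage-like cells went from 2.48 to 1.45 with thinned cells. The share of macrophage-like cells with a Retnla UMI was level, at 1.98% and 2.05% thinned and 5.01% and 4.77% unthinned, against 0.272% and 0.429% of thinned B-like cells. Lower were Hspa1b (3.04-fold, 2.63 to 3.53), Hspa1a (2.50-fold, 2.33 to 2.68), Gdf15 (2.57-fold, 2.21 to 2.99) and the T cell attractant Ccl5 (1.92-fold, 1.82 to 2.03). Il2rb, a gene of lymphocytes, was 2.11-fold (1.78 to 2.51) lower, and Ccl5 is also on the list of cytotoxic effectors of lymphocytes. Cells with markers of 2 lineages made up 13.9% and 12.9% of the class. Lymphocyte RNA was not excluded for either gene.

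The inflammatory cytokine and chemokine list split in macrophage-like cells, with 7 of 12 members higher (median 0.05, random deals -0.17 to 0.17). Il1b was 1.18-fold (1.16 to 1.21) higher and Ptgs2 1.33-fold (1.18 to 1.51) higher, whereas Tnf was 1.44-fold (1.30 to 1.60) lower and Ccl4 1.23-fold (1.19 to 1.27) lower. Oxidative phosphorylation genes were higher in 12 of 14 members (median 0.18, percentile 100, random deals -0.08 to 0.08), for example Cox4i1 (1.18-fold, 1.12 to 1.23) and Atp5b (1.14-fold, 1.06 to 1.22). Dissociation stress genes were lower in 14 of 16 members (median -0.29, percentile 0, random deals -0.12 to 0.13), among them Dnajb1 (1.62-fold, 1.43 to 1.84) and Jun (1.28-fold, 1.23 to 1.34). Cell cycle genes were higher in 12 of 14 members (median 0.40, random deals -0.37 to 0.37), with Mki67 at 2.12-fold (1.60 to 2.84), but the median was -0.04 with thinned cells. Lipid-associated (5 of 14 higher, median -0.05, random deals -0.14 to 0.15), tissue-resident (7 of 10 higher, median 0.08, random deals -0.55 to 0.53) and interferon genes (10 of 13 lower, median -0.22, random deals -0.34 to 0.37) lay within random deals. The interferon median was 0.03, and the lipid-associated one -0.12, with 2-lineage cells removed. The 12th gene each way, ranked without the 5% rule, had a bound of 1.34 (higher) and 0.562 (lower), against 1.32 and 0.709 in random deals.

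**Figure D2:**
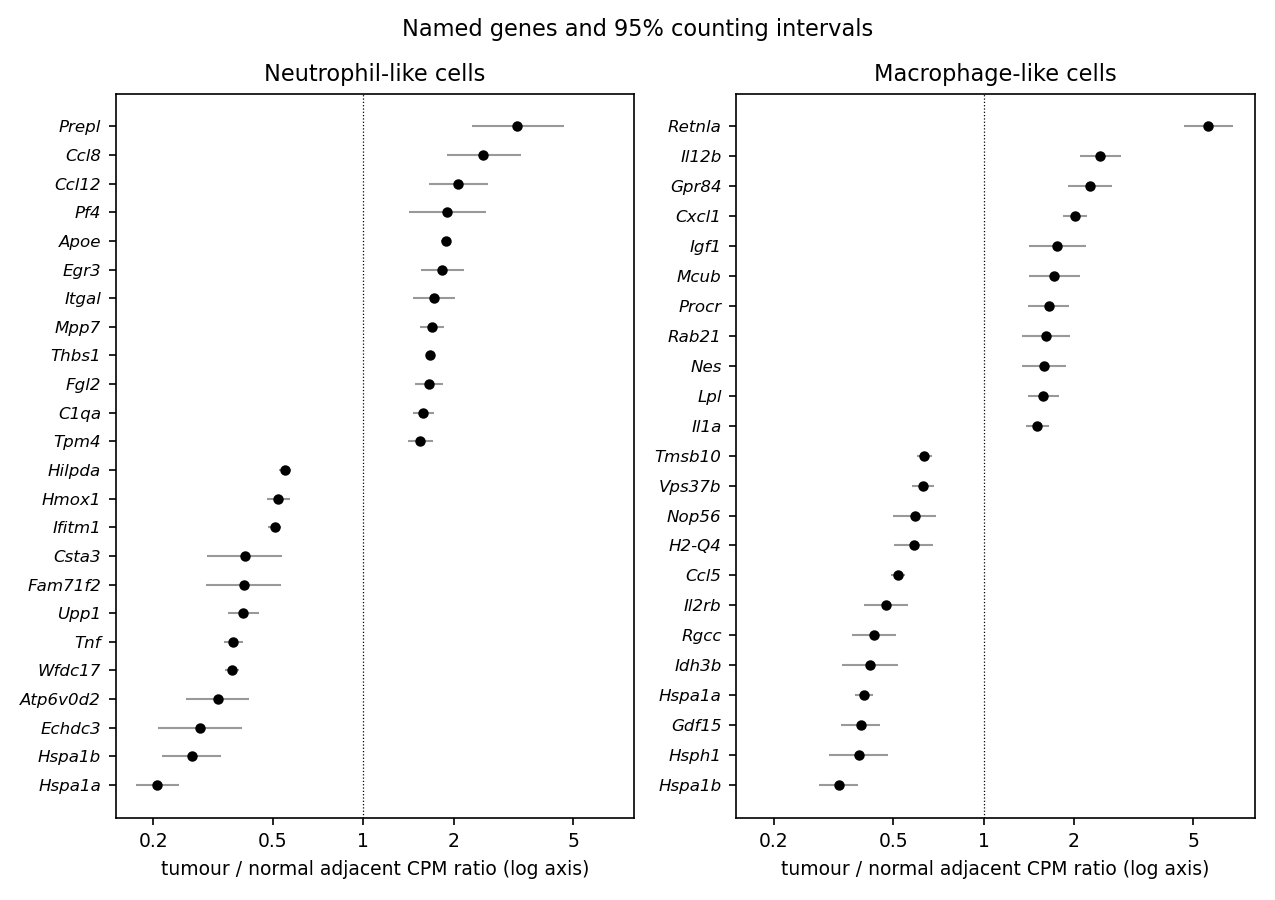
Ratio of tumour to normal adjacent CPM (log axis) for the named genes of neutrophil-like and macrophage-like cells, with exact 95% counting intervals as bars (Mucl1, found in 1 tumour macrophage-like cell and none of the normal adjacent ones, is not drawn). Hspa1a was 4.85-fold lower in neutrophil-like and 2.50-fold lower in macrophage-like cells.

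Monocyte-like cells of the tumour library had higher levels of interferon-induced genes and of genes of MHC class II antigen presentation. All 12 measured interferon genes were higher (median 0.96, percentile 100, random deals -0.41 to 0.51). Cxcl10 (ENSMUSG00000034855), a T cell attractant, was 3.92-fold (3.40 to 4.53) higher and Rsad2 (ENSMUSG00000020641) 3.28-fold (2.65 to 4.10) higher, and the log2 ratio of Rsad2 in monocyte-like cells went from 1.71 to 2.44 with thinned cells. Isg15 was 2.01-fold (1.79 to 2.26) higher and Gbp2 2.90-fold (1.97 to 4.36) higher. Cxcl9 was 12.1-fold (5.95 to 28.8) higher but found in 4 and 9 cells. The 9 genes of MHC class II antigen presentation were all higher (median 0.38, random deals -0.24 to 0.36), with H2-Ab1 at 1.36-fold (1.32 to 1.40) and Cd86 at 1.40-fold (1.21 to 1.62). Genes of MHC class I antigen presentation were higher (7 of 9 higher, median 0.16, random deals -0.11 to 0.10, percentile 97.9). The oxidative phosphorylation median lay outside random deals (10 of 14 lower, median -0.08, random deals -0.07 to 0.08) but within matched random lists (percentile 9.34). S100a8, a gene of neutrophils, was 1.89-fold (1.74 to 2.04) higher and the T cell gene Cd3e 1.67-fold (1.37 to 2.06) lower. Hmox1 was 2.04-fold (1.83 to 2.28) lower. Tnfrsf9 was 5.32-fold (3.95 to 7.28) lower and Gzma, a gene of cytotoxic lymphocytes, 11.4-fold (8.95 to 14.6) lower, a log2 ratio of -3.51 that was -2.72 for Gzma in monocyte-like cells with thinned cells. The share of thinned B-like cells with a Gzma UMI was also lower, at 5.72% and 1.72%. Cells with markers of 2 lineages made up 20.4% and 21.3% of the monocyte-like class. Lymphocyte RNA was not excluded for Tnfrsf9, Gzma or Cd3e. Cxcl1 was 8.96-fold (6.29 to 13.1) lower, and its direction turned, to a log2 ratio of 0.31, with 2-lineage cells removed. Nearly all normal adjacent Retnla UMIs of the class came from 1 cell. The fifth gene each way, ranked without the 5% rule, had a bound of 2.35 (higher) and 0.253 (lower), against 1.95 and 0.509 in random deals. Of the genes named here, Hmox1 had a bound nearer 1 than the dealt 0.509.

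Conventional dendritic-like cells of the tumour library had higher levels of Cxcl9, Ccl22 and Cd36 and lower levels of Tnfrsf9 and Cxcr6. Cxcl9 (ENSMUSG00000029417) was 1.83-fold (1.64 to 2.05) higher, Ccl22 (ENSMUSG00000031779) 1.75-fold (1.57 to 1.95) higher and Cd36, a fatty acid receptor, 1.79-fold (1.54 to 2.09) higher. Tnfrsf9 was 2.01-fold (1.79 to 2.26) lower, and Cxcr6, a chemokine receptor of T cells, 1.96-fold (1.71 to 2.26) lower. With 2-lineage cells removed the log2 ratio of Cxcr6 in conventional dendritic-like cells went from -0.97 to -1.65. Cell cycle genes were higher in all 14 members (median 0.75, percentile 100, random deals -0.28 to 0.35), with Mki67 at 1.84-fold (1.49 to 2.28) and Top2a at 1.86-fold (1.45 to 2.42), and the median was 0.26 with thinned cells. Inflammatory genes were higher in 10 of 13 members, within random deals (median 0.18, random deals -0.29 to 0.28). Dissociation stress genes were lower (11 of 16 lower, median -0.12, random deals -0.12 to 0.11). The neutrophil granule and suppressor list was higher in 12 of 13 members, within random deals (median 0.35, percentile 99.9, random deals -0.50 to 0.57). S100a8 was 2.13-fold (1.96 to 2.32) higher and Cd3e 1.37-fold (1.21 to 1.56) lower. Cells with markers of 2 lineages made up 42.1% and 43.5% of the class. Without the 5% rule, the fifth lower gene had a bound of 0.529 against 0.638 in random deals. The fifth higher gene, at 1.57, was not past the 1.57 of random deals. In migratory dendritic-like cells, Asph (2.15-fold, 1.66 to 2.80), Scin (2.07-fold, 1.62 to 2.65) and Ccnd1 (1.75-fold, 1.46 to 2.11) were higher and Cxcl9 (4.10-fold, 3.18 to 5.34) and Cd2 (2.39-fold, 1.72 to 3.38) lower. The log2 ratio of Cxcl9 in migratory dendritic-like cells was -2.03, and -1.13 without the top cell of each library. Random deals of these 115 and 147 cells gave bounds as far from 1 both ways. Their interferon (9 of 13 lower, median -0.25, random deals -0.42 to 0.54) and inflammatory genes (11 of 13 lower, median -0.27, random deals -0.68 to 0.61) lay within random deals. The inflammatory median was 0.06 with 2-lineage cells removed.

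CD8 T-like cells of the tumour library had lower levels of checkpoint and costimulatory receptors and of Gzma, and most of them carried transcripts of the trypsinogen gene Prss2. Prss2 (ENSMUSG00000057163) stood at 0.537 against 912 CPM, with 1 UMI in the normal adjacent library, a ratio of 1699 with an interval from 304 to 67196. At 1000 UMIs per cell, 0 of 280 normal adjacent CD8 T-like cells had a Prss2 UMI, which allows a share of up to 1.31%. Of the tumour ones 80 of 167 had one, or 47.9% (40.1 to 55.8). Thinning left out 31 and 13 cells, the unthinned shares were 0.322% and 59.4%, and 1.29% of thinned tumour B-like cells had one. Median depths were 5757 and 4932 UMIs in CD8 T-like cells. Gzma (ENSMUSG00000023132), a granzyme, was 9.29-fold (8.17 to 10.6) lower, and its thinned share was 27.1% and 8.98% (40.8% and 12.8% unthinned), against 5.72% and 1.72% in B-like cells. Penk (ENSMUSG00000045573), an opioid precursor, was 111-fold (30.5 to 919) lower, with 2 UMIs in the tumour library. Spp1 was 3.69-fold (2.93 to 4.70) lower, although 1 cell held 65.1% of its tumour UMIs. The log2 ratio of Spp1 in CD8 T-like cells went from -1.88 to -3.20 without the top cells and -0.83 in cluster 2 alone, and that of Prss2 in CD8 T-like cells from 10.73 to 7.42 in cluster 2 alone.

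Exhaustion and checkpoint genes were lower in 8 of 11 measured members (median -0.44, percentile 0, random deals -0.17 to 0.19, resampled members -1.06 to 0.14). Havcr2 was 4.48-fold (2.40 to 9.26) lower, Tnfrsf9 2.29-fold (2.01 to 2.62) lower, Lag3 2.09-fold (1.73 to 2.54) lower and Pdcd1 1.24-fold (1.05 to 1.48) lower, and Tox was 1.18-fold (1.01 to 1.38) higher. The thinned Havcr2 share was 4.29% and 0.599% (19.3% and 5% unthinned), against 0.817% and 0.429% of B-like cells (6.17% and 7.20% unthinned), so its tumour level was not above background. Thinned shares were 25.7% and 13.8% for Lag3 (63.3% and 40.6% unthinned, B-like 0.545% and 0.429%) and 22.1% and 15.6% for Pdcd1 (63.3% and 50.6% unthinned, B-like 1.36% and 2.15%). The list of activated regulatory T cells was lower in 5 of 6 members (median -0.84, percentile 0, random deals -0.27 to 0.21), with Tnfrsf4 at 4.28-fold (3.17 to 5.90) and Icos at 1.83-fold (1.47 to 2.29) lower. Interferon genes were higher in 8 of 11 members (median 0.72, percentile 100, random deals -0.29 to 0.29). An interval from resampled members, -0.30 to 0.80, included 0. Bst2 was 1.30-fold (1.07 to 1.58) higher, while Isg15 was 1.23-fold (1.06 to 1.44) lower. Cytotoxic effector genes had a median within random deals (-0.08, random deals -0.15 to 0.16), with Gzmb 1.35-fold (1.22 to 1.49) higher and Prf1 1.73-fold (1.34 to 2.27) lower. Prf1 was level, at a log2 ratio of -0.01 for Prf1 in CD8 T-like cells, with thinned cells. Genes of MHC class I antigen presentation (6 of 9 lower, median -0.16, random deals -0.07 to 0.08, percentile 12.9), hypoxia and glycolysis (8 of 12 lower, median -0.30, random deals -0.17 to 0.16, percentile 3.69) and oxidative phosphorylation (11 of 14 lower, median -0.11, random deals -0.08 to 0.10, percentile 22.5) lay below random deals but within matched random lists. Different clusters held the class in the 2 libraries. Cluster 2, whose leading genes include Penk, Lag3, Pdcd1 and Gzma, held 309 and 72 cells, and cluster 9, whose leading genes include Prss2, Trav4-4-dv10 and Gramd3, held 2 and 108. Cd8a, Cd8b1 and Gzmk were among the leading genes of both. In cluster 2 alone, Tnfrsf9 in CD8 T-like cells had a log2 ratio of -0.61 against -1.20, and Tox was level. The checkpoint median was -0.31 in cluster 2 alone and -0.07 with thinned cells. In the ranking without the 5% rule, the fifth lower gene had a bound of 0.324 against 0.468 in random deals. The fifth higher gene, at 1.63, was not past the 1.83 of random deals.

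**Figure D3:**
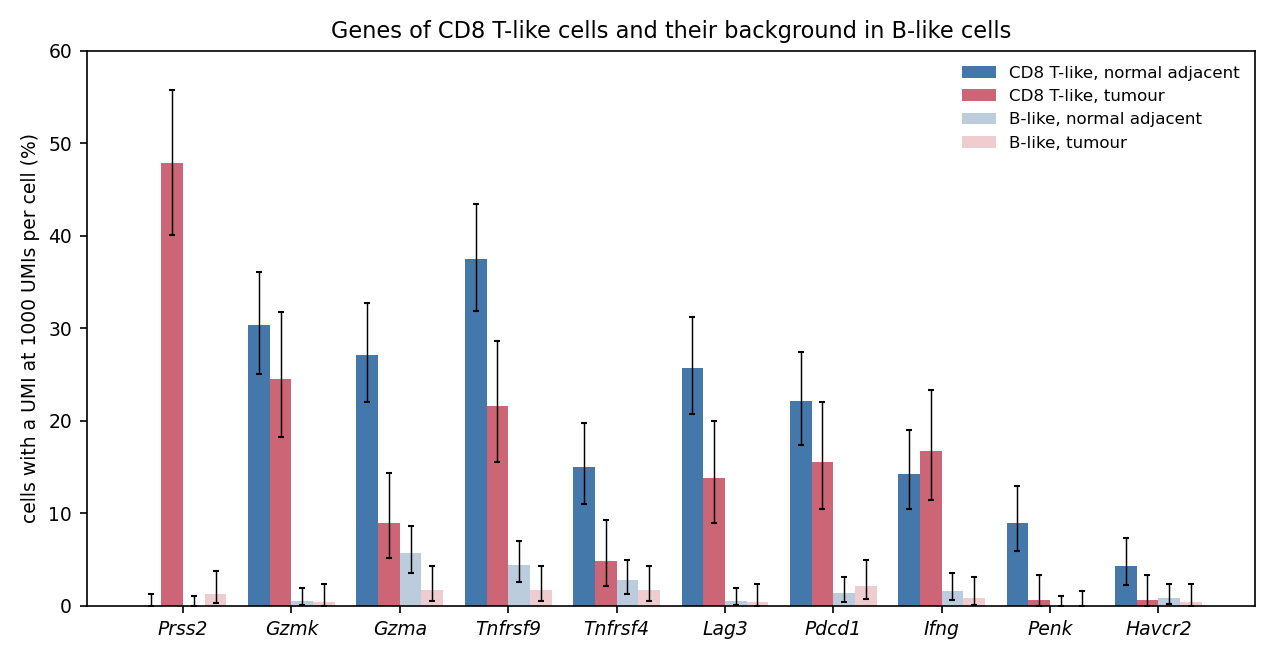
Share of CD8 T-like cells (%) with at least 1 UMI of 10 genes after thinning to 1000 UMIs per cell, in both libraries, beside the same share in B-like cells as background, with exact 95% intervals as bars. Prss2 was found in 0 of 280 and 80 of 167 cells, and Gzma in 27.1% and 8.98%.

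CD4 T-like and gamma delta T-like cells of the tumour library had higher medians of naive and memory T cell genes. Intervals from resampled members, -0.26 to 0.65 and -0.10 to 0.94, included 0. A cluster led by Lef1 and Ccr7 was kept out of both classes. It held 3.50% and 1.89% of immune cells, a difference of -1.61 points (-2.20 to -1.04). In CD4 T-like cells 5 of 8 members were higher (median 0.33, random deals -0.28 to 0.29), with Ccr7 at 1.79-fold (1.14 to 2.83) and S1pr1 at 1.31-fold (1.03 to 1.65). In gamma delta T-like cells 5 of 6 were higher (median 0.29, random deals -0.20 to 0.25), with Lef1 (ENSMUSG00000027985) at 2.64-fold (1.57 to 4.63) and Klf2 at 1.22-fold (1.05 to 1.41). Areg (ENSMUSG00000029378), a tissue repair factor, was 2.42-fold (1.58 to 3.77) higher in CD4 T-like cells and Ripor2 2.37-fold (1.47 to 3.88) higher. Plac8 was 7.58-fold (3.94 to 16.3) lower, although 1 cell held 40.9% of its normal adjacent UMIs, and the log2 ratio of Plac8 in CD4 T-like cells went from -2.92 to -4.84 with free RNA subtracted. Rgs16 was 3.14-fold (2.14 to 4.72) lower and Atf3 1.94-fold (1.42 to 2.70) lower. Cytotoxic effector genes were lower in 7 of 9 members of the CD4 T-like class, within random deals (median -0.47, random deals -0.63 to 0.55). Genes of MHC class II antigen presentation were lower in that class (6 of 8 lower, median -0.34, random deals -0.30 to 0.34). Free RNA and doublets were not excluded for this MHC class II list. Dissociation stress genes were lower in gamma delta T-like cells (15 of 16 lower, percentile 0, median -0.24, random deals -0.17 to 0.15). Their oxidative phosphorylation median lay at the edge of random deals (10 of 14 higher, median 0.07, random deals -0.08 to 0.07) and within matched random lists (percentile 90.1). In gamma delta T-like cells Pxdc1 was 1.83-fold (1.55 to 2.17) lower, Cxcr3 (ENSMUSG00000050232), a chemokine receptor, 2.17-fold (1.52 to 3.11) lower and Gpr65 2.02-fold (1.51 to 2.72) lower, while Ltb was 1.40-fold (1.26 to 1.55) higher and Dync1h1 2.0-fold (1.41 to 2.87) higher. Ranked without the 5% rule, the fifth lower gene was beyond random deals in both classes (0.555 against 0.634 in CD4 T-like, 0.646 against 0.721 in gamma delta T-like cells). The fifth higher gene was so in neither (1.44 against 1.58, 1.28 against 1.38). In NK-like cells Sh2d1a (2.0-fold, 1.41 to 2.85) and Lmna (1.64-fold, 1.37 to 1.98) were higher and Map3k8 (2.77-fold, 1.57 to 5.16) and the inhibitory receptor Klrc1 (2.05-fold, 1.43 to 3.0) lower, sizes that random deals of the same cells also reached. Tissue residency genes were lower in NK-like cells (5 of 6 lower, median -0.39, random deals -0.38 to 0.44). Their oxidative phosphorylation median lay at the edge of random deals (11 of 14 higher, median 0.09, random deals -0.10 to 0.09) and within matched random lists (percentile 94.6). Hspa1a was 3.76-fold (2.57 to 5.62) higher in NK-like cells, but 1 cell held 84.3% of its tumour UMIs, and without the top cells its log2 ratio turned to -0.30.

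B-like cells of the tumour library had higher levels of interferon genes, a difference that was smaller with 2-lineage cells removed. All 12 measured members were higher (median 1.02, percentile 100, random deals -1.0 to 0.96). Bst2 (ENSMUSG00000046718) was 2.07-fold (1.80 to 2.37) higher and Ifit3 4.35-fold (2.74 to 7.09) higher. The log2 ratio of Bst2 in B-like cells went from 1.05 to 0.23 with 2-lineage cells removed, and that of Ifit3 in B-like cells from 2.12 to 1.31 without the top cells. Isg15, 2.0-fold (1.67 to 2.41) higher, turned to a log2 ratio of -0.59 with 2-lineage cells removed. The list median was then 0.22, and 0.66 with thinned cells. Cells with markers of 2 lineages made up 19% and 25.8% of the class, and S100a8 (1.86-fold, 1.63 to 2.12) and C1qa, genes of neutrophils and macrophages, were also higher in it. Top2a was 3.16-fold (2.27 to 4.44) higher, with 48.5% of its tumour UMIs in 1 cell, and Asph 2.44-fold (1.87 to 3.21) higher. Cell cycle genes (12 of 13 higher, median 0.47, random deals -0.77 to 0.84) lay within random deals. Without the top cells the log2 ratio of Top2a in B-like cells was 0.81 against 1.66. Genes of T and NK cells were lower, namely Xcl1 (3.75-fold, 3.05 to 4.66) and Cd8a (3.80-fold, 2.64 to 5.62), and with 2-lineage cells removed the log2 ratio of Cd8a in B-like cells was -2.68 against -1.93. In the ranking without the 5% rule, the fifth higher gene had a bound of 2.27 against 2.22 in random deals. Asph, with a lower bound of 1.87, was not past 2.22. The fifth lower gene, at 0.508, was not past the 0.455 of random deals.

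Luminal progenitor-like cells of the tumour library had lower levels of hypoxia and glycolysis genes and of epithelial chemokines. Hypoxia and glycolysis genes were lower in 13 of 14 members (median -0.48, percentile 0, random deals -0.23 to 0.27), with Egln3 (ENSMUSG00000035105) at 2.06-fold (1.69 to 2.52), Bnip3 at 1.75-fold (1.44 to 2.14) and Gapdh at 1.62-fold (1.5 to 1.76) lower. Epithelial chemokines and cytokines were lower in 10 of 13 members (median -0.56, random deals -0.51 to 0.52). Ccl20 (ENSMUSG00000026166), which attracts lymphocytes and dendritic cells, was 36.1-fold (20.4 to 70.6) lower, from 7 and 6 cells, and Cxcl2 was 3.16-fold (2.96 to 3.39) lower, whereas Cxcl5 was 1.5-fold (1.32 to 1.71) higher. Higher were Gstm1 (ENSMUSG00000058135), a glutathione transferase, at 7.87-fold (6.68 to 9.32), the antimicrobial lectin Reg3g at 1.79-fold (1.72 to 1.87) and Dusp6 at 2.01-fold (1.69 to 2.41). With thinned cells the log2 ratio of Gstm1 in luminal progenitor-like cells was 1.65 against 2.98, that of Dusp6 in luminal progenitor-like cells 1.60 against 1.01 and that of Cxcl5 in luminal progenitor-like cells 1.49 against 0.59. Igfbp2, with 0 UMIs in the normal adjacent library, was at least 54.9-fold higher against a floor of 3 counts. It was found in 8 of 119 tumour cells, and in 4.20% (1.38 to 9.53) after thinning. All UMIs of Pip came from 1 cell. Stress genes were lower in 13 of 16 members (median -0.17, random deals -0.21 to 0.20) and interferon genes in 10 of 13 (median -0.33, random deals -0.56 to 0.63), both within random deals. The interferon median turned to 0.09 with thinned cells. Cholesterol and fatty acid synthesis genes were higher in 11 of 12 members, within random deals (median 0.40, random deals -0.33 to 0.42), and turned to -0.04 with thinned cells. The luminal progenitor list (8 of 12 higher, median 0.12, random deals -0.12 to 0.14) and the androgen response list (8 of 11 lower, median -0.05, random deals -0.32 to 0.26) also lay within random deals, as did epithelial-mesenchymal transition (5 of 6 higher, median 0.84, random deals -1.11 to 1.17). Random deals reached bounds as far from 1 as the 12th gene each way, ranked without the 5% rule. These were 2.13 against 1.74 (higher) and 0.483 against 0.537 (lower).

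Basal-like cells of the tumour library (58 and 114 cells) had higher levels of Spink5, Cxcl1 and Slc15a2. Spink5 (ENSMUSG00000055561), a serine protease inhibitor, was 7.69-fold (5.60 to 10.8) higher, Cxcl1 4.79-fold (3.19 to 7.49) higher and Slc15a2 3.90-fold (2.37 to 6.78) higher. With thinned cells the log2 ratio of Spink5 in basal-like cells was 3.83 against 2.94. Lower were Psca (4.66-fold, 3.67 to 5.95), Id3 (2.26-fold, 1.88 to 2.72) and Id1 (2.14-fold, 1.73 to 2.65). Wfdc18 was 31.7-fold (22 to 47.1) lower, but 1 cell held 98.4% of its normal adjacent UMIs, and without the top cells its log2 ratio turned to 0.71. Genes of epithelial-mesenchymal transition were higher in 5 of 7 measured members (median 0.46, random deals -0.41 to 0.44), with Snai2 at 1.54-fold (1.11 to 2.17), and the median turned to -0.28 with thinned cells. The luminal progenitor list (7 of 12 higher, median 0.23, random deals -0.36 to 0.32) and the interferon list (8 of 10 higher, median 0.29, random deals -1.01 to 1.42) lay within random deals, and the interferon median turned to -0.24 with thinned cells. Ranked without the 5% rule, the fifth higher gene had a bound of 3.19 against 2.76 in random deals. Slc15a2, with a lower bound of 2.37, was not past 2.76. The fifth lower gene, at 0.532, was not past the 0.302 of random deals. In fibroblast-like cells (54 and 81), Penk was 5.19-fold (4.48 to 6.03) higher, Sfrp4 4.18-fold (3.59 to 4.89) higher and Apod 2.84-fold (2.67 to 3.02) higher, and Sfrp2 was 4.03-fold (2.97 to 5.55) lower and Rorb 5.26-fold (3.44 to 8.31) lower. Sfrp4 led 1 of the 3 fibroblast-like clusters, with 26 and 55 cells, and Rorb and Sfrp2 another, with 10 and 4 cells. Without the top cells the log2 ratio of Rorb in fibroblast-like cells was -3.19 against -2.39. Random deals of the same cells gave bounds as far from 1, and the list of activated fibroblasts (9 of 13 higher, median 0.11, random deals -0.41 to 0.37) lay within them.

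**Figure D4:**
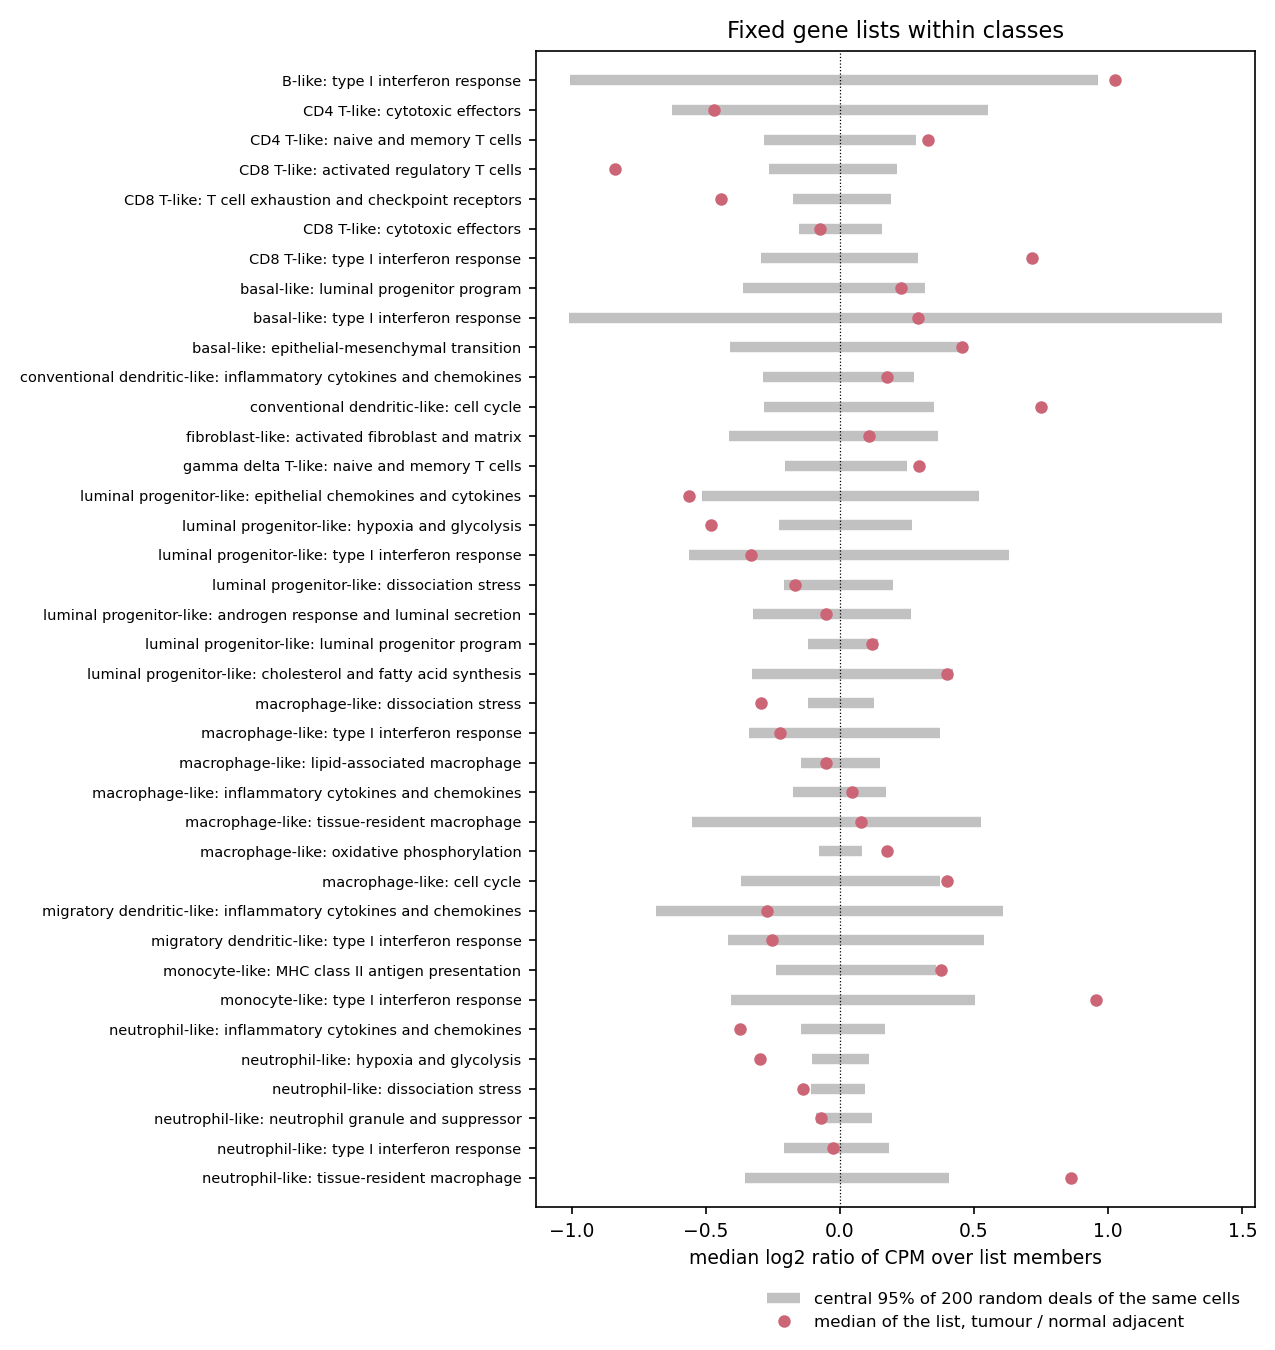
Median log2 ratio of tumour to normal adjacent CPM over the members of fixed gene lists, for 38 of the 147 lists by class, chosen after their values were seen (points), with the central 95% of medians from 200 random deals of the same cells (bars). Of these medians, 19 lay outside their bar, as did 14 of the 109 not drawn, and the farthest below 0 was that of activated regulatory T cell genes in CD8 T-like cells, at -0.84.

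A group of 3 genes, chosen after their values were seen, differed the same way in every class compared. Idh3b (ENSMUSG00000027406), a subunit of a mitochondrial dehydrogenase, was lower in the tumour library in 13 of 13 classes, with ratios from 0.296 to 0.704 and an interval that left out 1 in 12. Nop56 (ENSMUSG00000027405), a nucleolar protein gene, was lower in 13 of 13, with ratios from 0.314 to 0.593. Rab21 (ENSMUSG00000020132), a membrane traffic gene, was higher in 13 of 13, with ratios from 1.32 to 2.13. In gamma delta T-like cells Idh3b turned to a log2 ratio of 0.58 with thinned cells. Further genes were looked at across the classes, also chosen after their values were seen. Hspa1a was lower in 12 of 13 classes, with ratios from 0.206 to 0.687, and higher in NK-like cells only, where the value rested on 1 cell. Hspa1b was lower in 12 of 13 as well. Svs2, a seminal vesicle secretion gene, was higher in 13 of 13 classes, with ratios from 1.45 to 17.1. Both ends rested in part on 1 cell. Without the top cells the ratio was 2.27 in macrophage-like and 6.54 in NK-like cells, which need not be the ends of the range then. Jchain, a gene of antibody secretors, was higher in 13 of 13, and 2 classes had no normal adjacent UMI of it. Svs6, a second seminal vesicle gene, was lower in 13 of 13, from at most 8 tumour UMIs per class. Across the classes the neutrophil gene S100a8 was higher in 8 of 13, and the T cell gene Cd3e lower in 10 of 13. No explanation was tested for these further genes, from Hspa1a to Cd3e, and free RNA was not excluded for them.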

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

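The alternatives with cells of 2 lineages removed, the highest Scrublet scores removed, receptor genes and Prss2 left out, mixed clusters left out of the denominator, top cells left out and CD8 T-like cluster 2 alone were chosen after the data were seen. All other alternatives had been fixed before the data were examined, and each of these was run. No paired analysis was possible because each group has 1 library. Keeping doublets returned only 1 barcode and so tests nothing about doublets, and its values are left out of the counts that follow. The cells were clustered anew under it, which moved some classes. CD4 T-like cells then numbered 55 and 66, against 134 and 128. Monocyte-like cells stood at 2.44% and 2.42% of immune cells, the opposite sign to the main value. Of values for shares, 147 of 171 stayed within the counting interval, 23 moved beyond it and 1 turned. For single genes 2036 of 2280 values stayed, 229 moved and 15 turned. Thinned cells alone gave 96 of 211 that stayed, 111 that moved and 4 that turned, whereas at least 500 genes and a total without abundant and stress genes moved none of 293. For the 38 lists, set against an interval from resampled members, 254 of 270 stayed, 9 moved and 7 turned. Some of these intervals included no difference, so a list that stayed need not have kept its size. That of checkpoint genes in CD8 T-like cells ran from -1.06 to 0.14. Their median counted as stayed with thinned cells although it was far smaller. Turned counts only shares and genes whose interval left out the value of no difference, and lists outside the central 95% of random lists. The sign also changed for 22 values of shares, 13 of genes and 3 of lists that did not meet this. They were the gamma delta T-like (8 of 9 settings), monocyte-like (2) and macrophage-like (1) shares of immune cells and the fibroblast-like (8) and luminal progenitor-like (3) shares. The genes were Il1b and S100a9 in neutrophil-like, Spp1 and Fosb in macrophage-like, Ifng in CD8 T-like and Tcf7 in CD4 T-like cells, and the lists were interferon and granule genes in neutrophil-like cells. Another 93 values had too few UMIs to read, 13 of them with the opposite sign. The cause was not tested for any of the moves that follow.

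Differences of shares are given in percentage points. With a mitochondrial maximum of 10%, gamma delta T-like cells differed by 0.636 of immune and 7.49 of lymphoid cells. With at least 500 genes the values were 0.616 and 7.58, and NK-like cells differed by -2.44. At Leiden resolution 2, gamma delta T-like cells differed by 0.694 of immune and 6.79 of lymphoid cells, and CD4 T-like cells by -0.00083. With each library clustered alone, CD8 T-like cells differed by -1.94 of immune and -2.63 of lymphoid cells, gamma delta T-like cells by 0.869 and 7.55, CD4 T-like cells by -1.19 and regulatory T-like cells by -1.08, the last because no tumour cluster was named so. Under that setting neutrophil-like cells differed by 2.95 and macrophage-like cells by -6.86 of myeloid cells, and luminal progenitor-like cells by -5.69 of non-immune cells. With cells of 2 lineages removed, neutrophil-like cells differed by 8.65, macrophage-like by 3.34 and NK-like by -2.91. With receptor genes and Prss2 left out, plasma-like cells turned to -0.0168, and gamma delta T-like cells differed by 0.719 of immune and 7.58 of lymphoid cells. Without the clusters kept apart as mixed in the denominator, neutrophil-like cells differed by 8.86. The neutrophil-like, B-like, CD8 T-like and NK-like differences of immune cells had their direction under every alternative run.

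Single genes turned as follows, in log2 ratios. With cells of 2 lineages removed they were Isg15 in B-like cells (-0.59), Ifit1 in macrophage-like cells (0.032), Cxcl1 in monocyte-like cells (0.31), and Ccl7 (0.63), Cxcl2 (0.70) and Hspa1a (0.073) in migratory dendritic-like cells. With thinned cells they were Idh3b in gamma delta T-like cells (0.58), Akt1 in migratory dendritic-like cells (-0.35), and Isg15 (0.17) and Ltf (0.023) in luminal progenitor-like cells. Without the top cells they were Hspa1a in NK-like cells (-0.30), Wfdc18 in basal-like cells (0.71), Postn in fibroblast-like cells (0.15) and Clu in luminal progenitor-like cells (0.034). Clu in luminal progenitor-like cells also turned with a mitochondrial maximum of 10% (0.15).

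With thinned cells the median of interferon genes was 0.66 in B-like and 0.12 in neutrophil-like cells, and turned to 0.090 in luminal progenitor-like and -0.24 in basal-like cells. Under that setting the cell cycle median was 0.26 in conventional dendritic-like cells and turned to -0.037 in macrophage-like cells, cholesterol and fatty acid synthesis turned to -0.036 in luminal progenitor-like cells, and epithelial-mesenchymal transition turned to -0.28 in basal-like cells. Inflammatory genes in conventional dendritic-like cells stood at 0.061 when thinned and 0.082 with cells of 2 lineages removed. With cells of 2 lineages removed, interferon genes stood at 0.22 in B-like cells and turned to 0.034 in macrophage-like cells, and inflammatory genes turned to 0.062 in migratory dendritic-like cells. Lipid-associated genes stood at -0.12 and oxidative phosphorylation genes at 0.22 in macrophage-like cells. With a mitochondrial maximum of 10%, interferon genes stood at -0.52 in luminal progenitor-like cells. Depth limits thinned values most, since thinning left 82 of the 93 unread values with too few UMIs.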

Other observations

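All 7 tests of explanations given here were chosen after the result was seen, and the genes and clusters were picked out after their values were seen. Several clusters outside the named classes differed in share. A myeloid cluster led by Retnla and Lyz1 held 2.05% and 3.18% of immune cells in the normal adjacent and tumour libraries, a difference of 1.13 points (0.567 to 1.68), but 102 of its 116 and 190 of its 220 cells carried markers of 2 lineages, so doublets are not excluded. Cycling immune cells, of which 105 of 176 and 151 of 293 carried markers of 2 lineages, held 3.11% and 4.23%, and a lymphoid cluster led by Cd7 and the Ly49 receptor genes Klra7 and Klra1 held 4.31% and 3.06%. A lymphoid cluster led by the granzyme genes Gzmf and Gzmc held 4.70% and 3.32%. Among non-immune cells, a cluster was led by Atp6v1g3, Clcn5 and Foxi1, genes of ion-transporting intercalated-type cells. It held 0 of 550 normal adjacent cells, which allows a share of up to 0.668%, and 14 of 842 tumour cells. A cluster led by Sbp and Spink1 held 36 and 20 cells, or 6.55% and 2.38%. A cluster found mostly in 1 library may be a property of that library, and no value here tells the difference, as for the 13 classes in which Idh3b, Nop56 and Rab21 moved alike.

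Prss2, a trypsinogen gene, had UMIs in 107 of 180 tumour CD8 T-like cells and 1 of 311 normal adjacent ones. Free RNA in every droplet is argued against by the share of thinned tumour B-like cells with a Prss2 UMI, 1.29%, against 47.9% of thinned CD8 T-like cells. Pancreatic acinar cells or their RNA are argued against by 18 other acinar genes, which together gave 1 UMI against 829 of Prss2 in those cells, or 0.121%. An expanded T cell clone stays open and is in line with the receptor segments: Trav4-4-dv10 had a UMI in 73.8% (64.4 to 81.9) of cells with Prss2 and 8.22% (3.08 to 17) of cells without, and Trbc1 in 2.80% and 54.8%. Prss2 lies next to Trbd1 in the T cell receptor beta locus in GENCODE vM21, and 56 of 293 tumour cycling cells had a Prss2 UMI against 1 of 176 normal adjacent ones, while a tumour effect was not tested.

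Idh3b and Nop56 were lower and Rab21 higher in the tumour library in all 13 classes compared. Free RNA from 1 cell type is argued against by their levels outside the class with the highest level, where the lowest of the 3 genes' medians was 29.9% of that class. A difference in animal, strain or library preparation cannot be told apart from tumour against normal adjacent tissue, because 13 of 13 classes moved alike and each group has 1 library. Idh3b and Nop56 overlap on opposite strands in GENCODE vM21. A biological difference between the tissues stays open as untested.

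Tissue-resident macrophage genes were higher in tumour neutrophil-like cells, with a median log2 ratio of 0.86 over 8 members. For this list a rise of free RNA alike in every droplet is argued against by B-like cells, in which 6 measured members had a median of 0.068. B-like cells cannot show whether free RNA weighed more in shallower cells. Their median depths were 5122 and 5250 UMIs, against 2920 and 2304 in neutrophil-like cells. That part of a free RNA explanation stays open. Free RNA also stays open for the macrophage gene C1qa, which is outside the list. C1qa was 1.51-fold higher in B-like cells against 1.58-fold in neutrophil-like cells. C1qa was also higher in CD8 T-like (ratio 1.39, 1.14 to 1.70), conventional dendritic-like (1.26, 1.20 to 1.32) and monocyte-like cells (1.24, 1.17 to 1.32). B-like cells held 19% and 25.8% 2-lineage cells, and C1qa was not higher beyond its interval in CD4 T-like (ratio 0.772, 0.568 to 1.04), gamma delta T-like (1.05, 0.850 to 1.29) or NK-like cells (1.10, 0.835 to 1.44). Doublets of neutrophils and macrophages cannot be told apart from a change within neutrophils, since the median was 0.77 with cells of 2 lineages removed but 717 tumour neutrophil-like cells with a macrophage UMI were left. A biological difference between the tissues stays open as untested.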
